A study of Vitis vinifera
Botrytis cinerea and Vitis vinifera with 16 samples.

How the data were processed

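RNA was measured in ripe berries of the white grapevine cultivar Sémillon, collected in the field with and without natural infection by the grey mould fungus Botrytis cinerea. Per the labels' protocols, polyadenylated RNA was sequenced after a CTAB extraction and the Illumina TruSeq v2 preparation, which does not mark strand. The 16 libraries form 4 groups of 4, taken from the sample titles: Control berries had no visible symptoms, and Stage1, Stage2 and Stage3 are 3 distinct stages of noble rot, whose symptoms the labels do not describe. Each library is a separate pool of 10 to 15 berries from neighbouring vines, per the series design, so the spread between libraries is a spread between pools of 1 site. The labels warn that other environmental organisms may be present in the pools.

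The authors deposited 1 table of raw read counts per gene for all libraries, per the file headers and the values, which are whole numbers with a different total in each library. Bowtie2 2.1.0 is named in the submitters' processing notes. The counting tool, the gene models' build, the handling of reads that match several genes and the strand setting are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes are therefore uncertain, since their reads could have been split or lost. The table holds 46774 features, of which 29971 have identifiers starting with VIT, 16448 with BC1T and 355 with BcDW1. No feature was without an identifier.

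The table does not pair identifiers with names or organisms. The reference table of grapevine genes used here held 0 of the identifiers, so no gene names and no coordinates are given. Features starting with VIT were treated as grapevine and all others as fungal. This is an assumption from the identifiers, set beside the counts: VIT features held all but 0.0874% to 1.46% of counts in symptomless berries, and the other features held 80.5% to 91.2% at Stage3. Lists of grapevine pathways and of other tissues' markers had been fixed before the data were examined, as name patterns. Without names they had no members, and none was tested.

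Grapevine and fungal genes were analysed apart, each with the counts of its own organism as library size. Grapevine genes were fitted over all 16 libraries and fungal genes over the 12 infected ones, with a mean per group. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, robust fit, two-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter left 15876 grapevine genes with 99.8% of grapevine counts and 10773 fungal genes with 99.89% of fungal counts. Standard errors of log2 fold changes are approximations, the absolute log2 fold change divided by the square root of F. CPM values are counts scaled to the total of the organism's own tested genes after TMM, in the usual unit of that name, and M denotes 1000000 counts. They are relative within each organism and do not measure its amount of RNA.

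The fungal share of counts was compared by exact permutation tests on the log10 share, two-sided, over all 70 assignments of 4 against 4 libraries, with Benjamini-Hochberg adjustment over 6 pairs of groups. The smallest p these tests allow is 0.0286. Binomial intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and figures were drawn with matplotlib 3.10.9.

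The rule for named genes, fixed before the data were examined, took the most extreme log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and every pool of one group above every pool of the other. It also required a functional name. As no names were found, that condition was dropped and at most 2 identifiers in each direction are given per comparison. A fold against a group with 1 to 3 counts is given with its counting interval at 95%. Log2 fold changes come from the edgeR fit and not from these count ratios, so they can differ from them. Their approximate standard errors do not stand in for the counting interval. A fold against a group at 0 is a lower bound computed from 3 counts over all 4 libraries of that group.

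The edgeR procedure was tested on simulated counts with 200 changed genes in each comparison. For grapevine genes it recovered 97% of 4-fold changes in Stage1 against Control, 87% in Stage2 against Control, 85% in Stage3 against Control, 93% in Stage2 against Stage1 and 83% in Stage3 against Stage2. It recovered 55% of 2-fold changes in Stage3 against Stage2. For fungal genes it recovered 91% of 4-fold changes in Stage2 against Stage1, 95% in Stage3 against Stage2 and 90% in Stage3 against Stage1. False calls made up 2.1% to 6.7% of calls. The simulated changes were few and went up and down in equal numbers, from a level common to all groups. These rates therefore do not test the scaling where many genes change, as in Stage2 and Stage3 against Control.

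No libraries of a group agreed within sampling noise: chi-square per degree of freedom over genes was 2.58 or more in grapevine and 8.92 or more in fungal genes. Groups share the pool numbers 1 to 4, and it was checked whether equal numbers deviate together. For Stage1 and Control the correlations across genes of the deviations from the group means were 0.31, 0.32, 0.27 and 0.19 for numbers 1 to 4, all above the limit of 0.1 set for pairing. The numbers met that limit, although only 2 of the 4 correlated best with themselves. Different numbers that were both odd or both even had correlations of 0.21 to 0.41, and an odd with an even number -0.39 to -0.20. The deviations therefore went with odd or even numbers and not with single pool numbers. The labels do not say that a number marks a shared vine or day. No other pair of groups met that limit.

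Alternatives fixed beforehand were RLE scaling, library totals without TMM, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of at least 5 CPM in at least 4 libraries, a fit of the 8 compared libraries, the pool number as a replicate block, thinning to the smallest total, and leaving out each library. Alternatives added after the data were seen left out Control replicates 1 and 4, which held the most fungal counts among Controls, or kept the odd-numbered or the even-numbered pools of Control and Stage1. The genes with a count, the share of the 10 most abundant genes, that of 100 genes as its alternative, and sign-flip tests of both measures over same-numbered pools were also added after the data were seen.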

Results

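Noble rot is the slow infection of ripe grapes by Botrytis cinerea used for sweet wines. Gene counts were obtained from pools of Sémillon berries without visible symptoms and at 3 stages of noble rot, with 4 pools in each of 4 groups. Every library held reads of the grapevine and of the fungus. Total counts were 19.1 ± 1.79 M counts in Control, 16.0 ± 2.97 M in Stage1, 13.4 ± 3.18 M in Stage2 and 13.7 ± 1.66 M in Stage3 (mean ± SD, n = 4 each), and single libraries ranged from 8.77 to 20.9 M. Grapevine counts fell from 18.9 ± 1.81 M in Control to 13.6 ± 3.79 M in Stage1, 3.69 ± 1.37 M in Stage2 and 1.94 ± 0.457 M in Stage3. Grapevine changes at the later stages therefore rest on fewer counts, with a minimum of 1.30 M in Stage3 replicate 3. Genes are given by the identifiers of the deposited table, which were not paired with names.

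The fungal share of counts measured how much of the sequenced RNA came from the fungus. It was 0.648 ± 0.661% in Control, 15.9 ± 8.77% in Stage1, 73.0 ± 5.71% in Stage2 and 85.6 ± 4.52% in Stage3 (mean ± SD, n = 4). The ratio of geometric means was 38.5 for Stage1 over Control, 5.39 for Stage2 over Stage1 and 1.17 for Stage3 over Stage2. The first was 24.2 without Control replicate 2 and 61.9 without Control replicate 4. Without the 9522 fungal genes that had a count in Control, the others were 17.7 and 2.45. Those genes left the total as well as the fungal counts, so this is a different measure. Its larger ratios do not show that background had hidden a rise. No library of a later stage overlapped with an earlier one, although the lowest Stage3 share, 80.5%, lay close to the highest Stage2 share, 78.7%. Each of the 6 pairs of groups gave an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.0286. Symptomless berries were not free of fungal counts. Their shares were 0.920% (95% Clopper-Pearson interval 0.915 to 0.924%) in Control replicate 1, 0.0874% (0.0861 to 0.0886%) in replicate 2, 0.129% (0.128 to 0.131%) in replicate 3 and 1.46% (1.45 to 1.46%) in replicate 4.

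**Figure D1:**
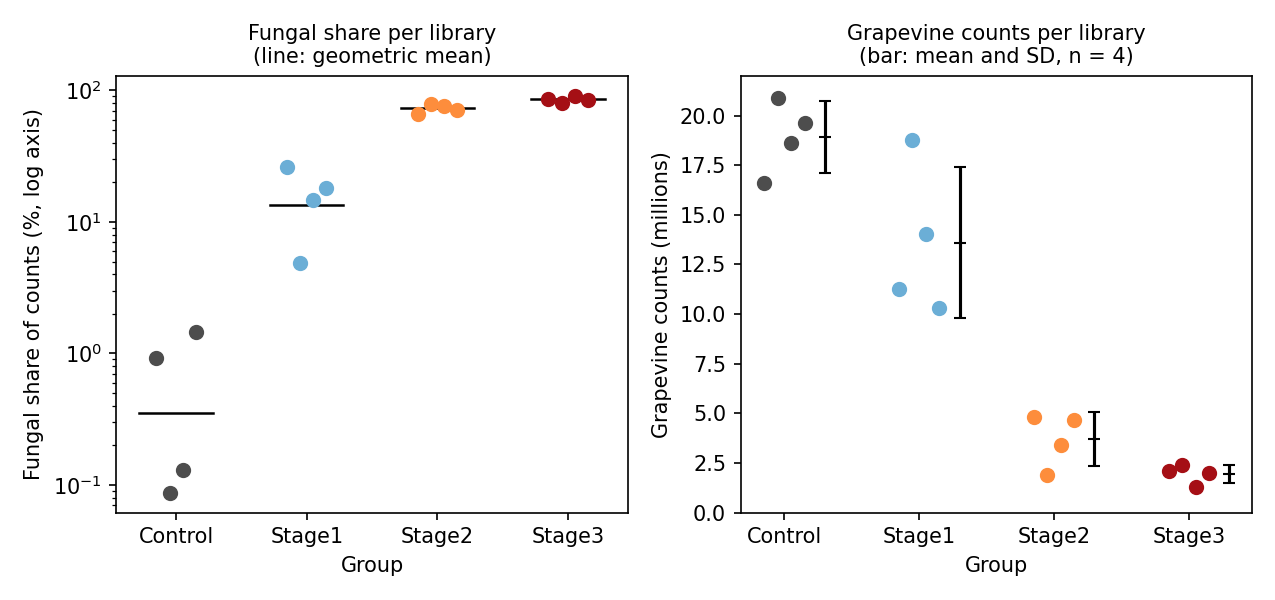
Left, the percentage of counts on fungal genes on a log axis, 1 point per library and a line at the geometric mean of each group; right, grapevine counts in Ms per library with mean and SD (n = 4). Fungal shares rose from at most 1.46% in Control to at least 80.5% in Stage3, while grapevine counts fell to 1.94 M on average.

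Stage1 against Control asked how the berry transcriptome differed at the lowest numbered stage. Of 15876 grapevine genes, 1790 were higher and 538 were lower in Stage1, and 1144 and 158 of them changed at least 2-fold. The number of lower genes was less stable: it was 351 and 271 without Control replicates 1 and 3, 285 and 334 without Stage1 replicates 2 and 4, 950 with DESeq2 and 1074 with limma-voom. VIT_18s0117g00590.t01 had 6.17 ± 2.07 CPM in Stage1 and 0.0121 ± 0.0241 CPM in Control (mean ± SD, n = 4), where it held 1 count in all, a ratio of 544 with a counting interval of 97.0 to 21500 (log2 fold change 8.04 ± 0.57 SE, adjusted p = 1.9e-08). VIT_06s0009g02560.t01 rose 141-fold, from 0.245 ± 0.293 to 34.5 ± 9.50 CPM (log2 fold change 7.15 ± 0.71 SE, adjusted p = 6.65e-06). The decreases were smaller. VIT_13s0067g02930.t01 was at 229 ± 179 CPM in Control and 39.2 ± 24.4 CPM in Stage1 (log2 fold change -2.55 ± 0.68 SE, adjusted p = 0.0203), and VIT_06s0004g06830.t01 at 41.2 ± 29.7 and 7.64 ± 4.41 CPM (log2 fold change -2.44 ± 0.75 SE, adjusted p = 0.0433). Both calls depended on single libraries, while the log2 fold changes over 20 alternatives were -2.96 to -2 and -2.99 to -1.83. Without Control replicate 3, Stage1 replicate 2 or Stage1 replicate 4, VIT_13s0067g02930.t01 had an adjusted p of 0.0625 to 0.0776, and without any library but Control replicate 4, VIT_06s0004g06830.t01 had 0.0528 to 0.162. The former was also not called in even-numbered pools alone, an alternative chosen after the data were seen (adjusted p = 0.106, with 0.00104 to 0.106 over all alternatives). The call of VIT_06s0004g06830.t01 was also lost in odd- or even-numbered pools alone (adjusted p = 0.325 and 0.214), with the pool number as a replicate block (adjusted p = 0.0561), without the filter (0.0685) and at equal depth (0.0889), and over all alternatives its adjusted p was 0.00827 to 0.325. At equal depth, which left 11129 genes to test, 994 were higher and 251 lower.

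Stage2 against Control asked the same of berries in which most counts were fungal. There were 4594 grapevine genes higher and 4700 lower, 58.5% of the genes tested, and 2315 and 2583 of them changed at least 2-fold. VIT_05s0062g00310.t01 rose from 0.121 ± 0.0969 CPM in Control to 147 ± 57.2 CPM in Stage2, a 1220-fold change (log2 fold change 10.17 ± 0.71 SE, adjusted p = 3.39e-08). VIT_05s0062g00300.t01, whose identifier closely precedes it, rose 1090-fold to 53.0 ± 33.6 CPM (log2 fold change 9.83 ± 0.77 SE, adjusted p = 7.47e-08). Whether the counting could split reads between this pair is not known. VIT_01s0026g02620.t01 fell from 130 ± 50.6 to 3.11 ± 3.07 CPM, a 41.8-fold change (log2 fold change -5.69 ± 0.45 SE, adjusted p = 6.61e-08). VIT_01s0010g03620.t01 fell from 6.30 ± 5.81 CPM to 1 count in the 4 Stage2 libraries, a ratio of 77.8 with a counting interval of 13.9 to 3080 (adjusted p = 0.00258). The split of directions depended on the scaling: 49.4% of calls were higher with TMM, 47.4% with RLE scaling and 25.9% with library totals only. Library totals lowered the median log2 fold change of all genes by 0.41. At equal depth, 5882 of 11129 genes tested were called.

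Stage3 against Control gave 4278 grapevine genes higher and 4599 lower, with 2034 and 2656 of them changed at least 2-fold. VIT_07s0005g02070.t01 was at 34.7 ± 3.65 CPM in Stage3 and held 2 counts in the 4 Control libraries, a ratio of 1500 with a counting interval of 411 to 12500 (log2 fold change 9.95 ± 0.40 SE, adjusted p = 6.25e-13). VIT_18s0117g00590.t01, also among the largest increases at Stage1, reached 15.2 ± 5.73 CPM, a ratio of 1390 to the 1 Control count with a counting interval of 245 to 55400 (log2 fold change 9.38 ± 0.58 SE, adjusted p = 2.03e-10). VIT_02s0025g02620.t01 and VIT_13s0074g00700.t01 had 10.2 ± 2.56 and 10.1 ± 2.59 CPM in Control and 0 counts in Stage3, and were each at least 23.6-fold lower against a floor of 3 counts over the 4 Stage3 libraries (adjusted p = 0.000132 and 2.18e-07). Of the calls, 48.2% were higher with TMM and 27.6% with library totals only, which shifted the median by -0.33. At equal depth, 5889 of 11129 genes tested were called.

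**Figure D2:**
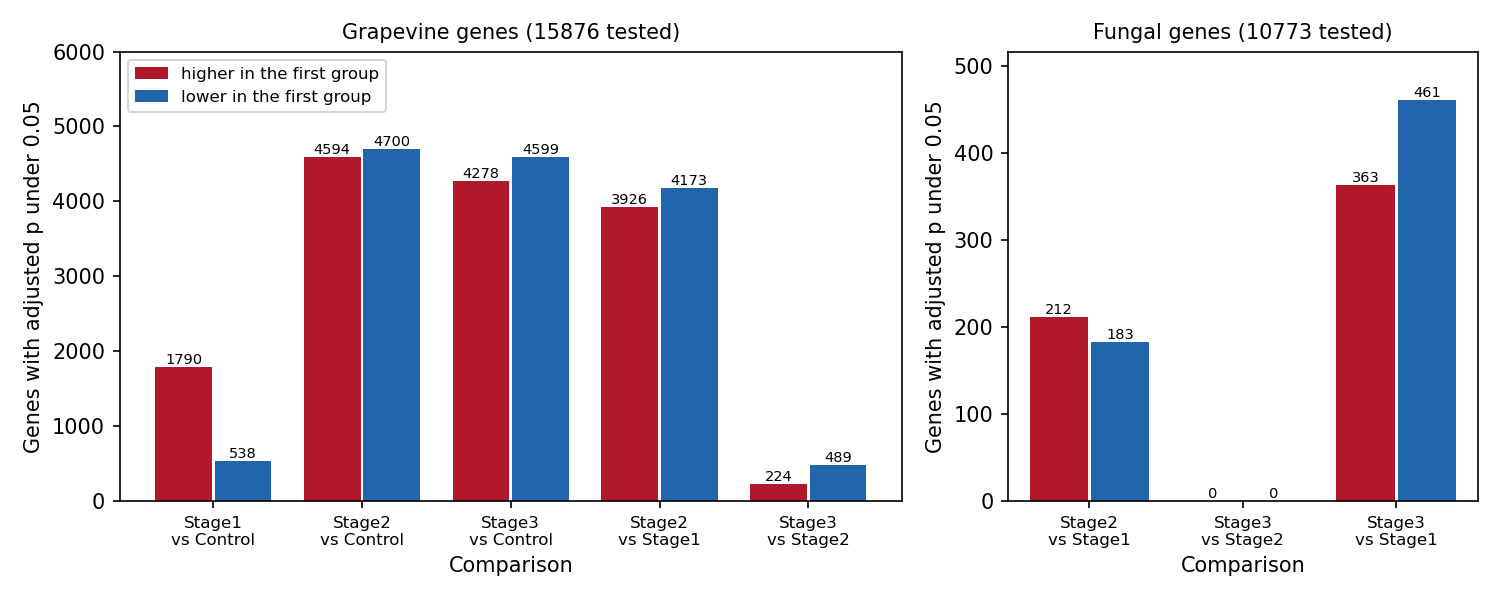
Genes with adjusted p under 0.05 in each comparison, split into genes higher and lower in the group named first, for 15876 grapevine genes (left) and 10773 fungal genes (right); the vertical axes differ. Grapevine calls were most numerous in Stage2 against Control, and no fungal gene was called in Stage3 against Stage2.

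Stage2 against Stage1 and Stage3 against Stage2 compared neighbouring stages of the rot. Between Stage1 and Stage2, 3926 grapevine genes rose and 4173 fell. VIT_07s0005g03420.t01 had 34.0 ± 53.3 CPM in Stage2 and 2 counts in the 4 Stage1 libraries, a ratio of 626 with a counting interval of 172 to 5200 (log2 fold change 9.43 ± 1.58 SE, adjusted p = 0.000273), and its Stage2 pools ranged from 0.753 to 114 CPM. VIT_05s0020g03530.t01 rose 78.6-fold to 64.3 ± 62.9 CPM (log2 fold change 6.14 ± 0.98 SE, adjusted p = 0.000189). VIT_19s0085g00740.t01 and VIT_08s0040g00920.t01 stood at 11.8 ± 9.08 and 10.2 ± 6.65 CPM in Stage1, and fell to 1 and 3 counts in all of Stage2, ratios of 155 (counting interval 27.8 to 6140) and 41.2 (14.0 to 201) (adjusted p = 0.000772 and 0.000129). Their Control levels were 0.616 ± 0.661 and 0.0974 ± 0.113 CPM, below those of every Stage1 pool. Of the calls, 48.5% were higher with TMM and 22.8% with library totals only, which shifted the median by -0.36. At equal depth, 5061 of 11129 genes tested were called.

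Between Stage2 and Stage3 fewer grapevine genes were called: 224 rose and 489 fell, and 62 and 84 of them changed at least 2-fold. VIT_03s0038g03860.t01 rose from 22.1 ± 11.7 to 82.9 CPM (65.8 to 113 CPM, n = 4) (log2 fold change 1.87 ± 0.38 SE, adjusted p = 0.0176), next to 95.5 ± 24.8 CPM in Control. VIT_00s1328g00020.t01 rose from 1.44 ± 0.314 to 5.48 ± 1.75 CPM (log2 fold change 1.91 ± 0.48 SE, adjusted p = 0.0306). VIT_04s0008g03930.t01 fell from 76.1 ± 72.1 to 11.7 ± 4.27 CPM (log2 fold change -2.60 ± 0.62 SE, adjusted p = 0.0358), and VIT_08s0007g03420.t01 from 7.51 ± 6.04 to 0.917 ± 0.526 CPM (log2 fold change -2.98 ± 0.77 SE, adjusted p = 0.0342). These calls lay near the threshold. VIT_03s0038g03860.t01 lost its call without Stage3 replicate 1 (adjusted p = 0.0515), VIT_00s1328g00020.t01 without any library but Stage2 replicate 4 and Stage3 replicate 3 (0.0528 to 0.112), VIT_04s0008g03930.t01 without Stage2 replicate 1 or Stage3 replicates 1, 2 or 3 (0.0556 to 0.105), and VIT_08s0007g03420.t01 without any library but Stage2 replicates 1 and 4 (0.0603 to 0.106). The 713 calls became 281 without Stage2 replicate 1, 325 without Stage2 replicate 3, and 177, 297 and 275 without Stage3 replicates 1, 2 and 3, and the 224 higher genes became 139 and 366 without Stage2 replicates 2 and 4. limma-voom lost the calls of VIT_00s1328g00020.t01, VIT_08s0007g03420.t01 and VIT_04s0008g03930.t01 (adjusted p = 0.0657, 0.221 and 0.170). The fit of 8 libraries lost those of VIT_03s0038g03860.t01 and VIT_04s0008g03930.t01 (0.0603 and 0.110). The call of VIT_04s0008g03930.t01 was also lost without the filter (0.0626) and with the pool number as a replicate block (0.0781). DESeq2 called 1192 genes, limma-voom 116 and the fit of 8 libraries 466, of which 45.3% were higher. The share of calls that were higher was 31.4% with TMM and 52.7% with library totals only.

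**Figure D3:**
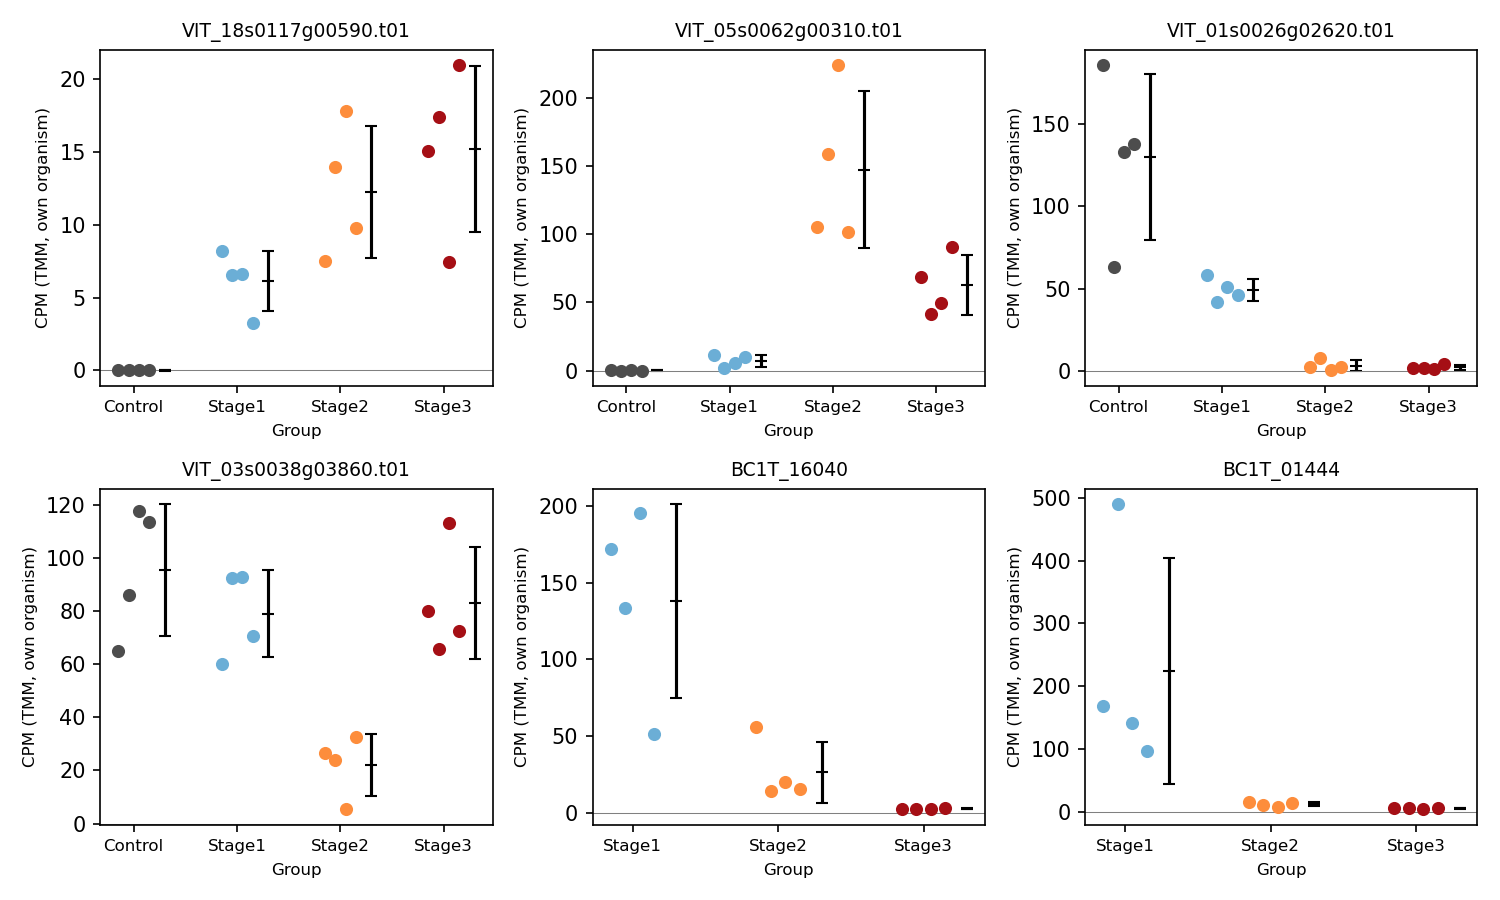
CPM within each organism for 4 grapevine and 2 fungal genes, 1 point per library, with mean and SD (n = 4) at the right of each group. VIT_18s0117g00590.t01 rose from 0.0121 CPM in Control to 15.2 CPM in Stage3, and BC1T_16040 fell from 138 CPM in Stage1 to 2.59 CPM in Stage3.

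Genes called at Stage1 were mostly called in the same direction later. Of the 1790 genes higher at Stage1, 1544 were higher at Stage2 (518 for independent lists) and 1556 at Stage3 (482.3 for independent lists). Of the 538 lower genes, 382 were lower at Stage2 (159.3 for independent lists) and 383 at Stage3 (155.8 for independent lists). Stage2 and Stage3 shared 3656 higher and 3568 lower genes (1237.9 and 1361.5 for independent lists), and 3068 to 3177 and 2872 to 3040 with Controls split 2 and 2 (896.5 to 1016.5 and 980.4 to 1101.4 for independent lists). All stages used the same Control libraries, and 20 simulations of unchanged stages against those libraries gave 0 shared genes. As these simulations called 0 genes at all, that value does not show how shared Controls act on lists with changed genes. With Controls split 2 and 2, the Stage1 and Stage2 lists shared 1106 to 1325 higher genes, where independent lists would share 309.1 to 408.2. The lower genes varied more, from 136 to 422 for Stage1 and Stage2 (49.1 to 188.6 for independent lists) and from 132 to 414 for Stage1 and Stage3 (47.6 to 181.8 for independent lists). Between Stage1 and Stage2, 954 of the 1790 genes rose further and 196 fell (442.7 and 470.5 for independent lists). Both comparisons used the same Stage1 libraries, and these numbers depend on the scaling. The share of Stage2 against Stage1 calls that were higher was 48.5% with TMM and 22.8% with library totals only.

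**Figure D4:**
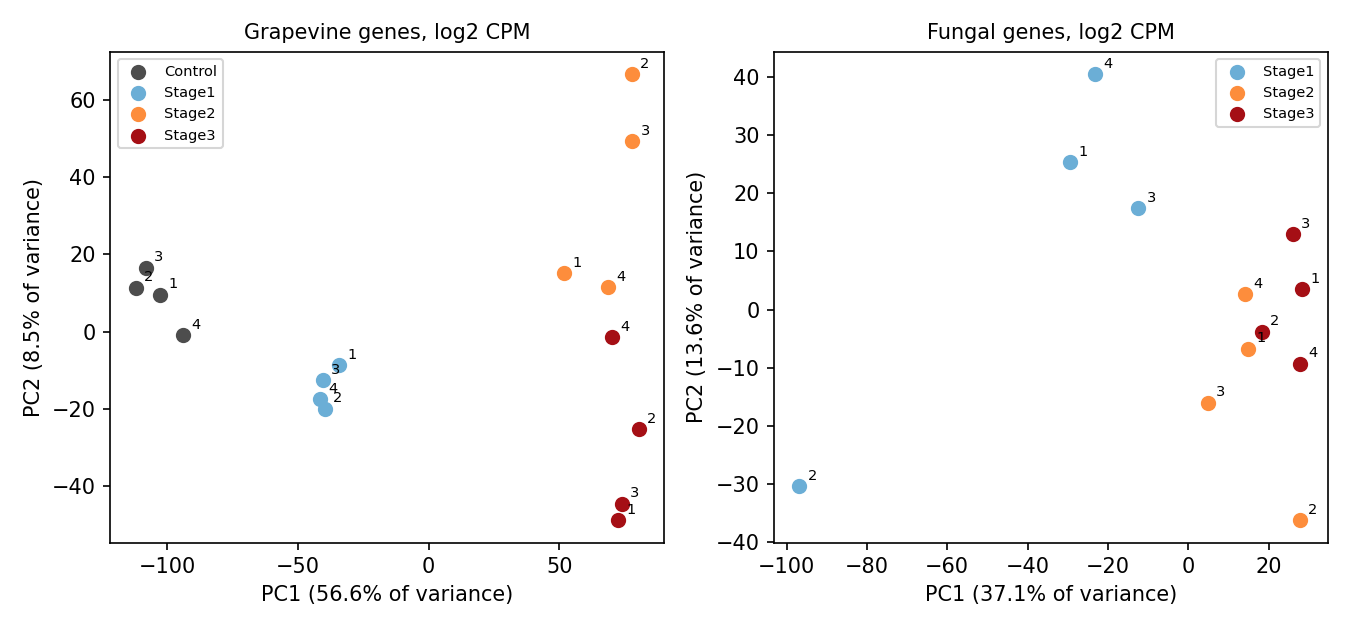
First and second principal components of log2 CPM of grapevine genes (left) and fungal genes (right), with points coloured by group and numbered by replicate. Grapevine libraries spread along the first component (56.6% of variance) from Control (-112.1 to -93.8) over Stage1 to Stage2 and Stage3 (52.0 to 80.4). Among fungal profiles, Stage1 replicate 2 lay lowest on the first component, at -96.8. It also held the fewest fungal counts of the infected libraries, 0.957 M, and what depth adds to its position was not tested.

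Fungal genes were compared between infected stages. Grapevine reads counted on fungal genes would give decreases as the ratio of fungal to grapevine counts rose. This ratio rose by 4.09 on the log2 scale from Stage1 to Stage2, a size near that of the decreases named here. Such reads were not tested for and stay open. Of 10773 genes, 212 were higher and 183 lower in Stage2 than in Stage1. BC1T_09180 rose from 17.4 ± 18.9 to 422 ± 279 CPM (log2 fold change 4.57 ± 1.08 SE, adjusted p = 0.0404) and BC1T_13094 from 0.551 ± 0.653 to 10.2 ± 5.85 CPM (log2 fold change 4.17 ± 0.73 SE, adjusted p = 0.0105). BC1T_06310 fell from 39.6 ± 32.1 to 1.54 ± 0.83 CPM (log2 fold change -4.57 ± 0.62 SE, adjusted p = 0.00477) and BC1T_02326 from 13.1 ± 9.27 to 0.706 ± 0.153 CPM (log2 fold change -4.22 ± 0.86 SE, adjusted p = 0.0233). The call of BC1T_09180 was lost without any library but Stage1 replicate 3 and Stage2 replicate 3 (adjusted p = 0.0539 to 0.110), and that of BC1T_02326 without Stage1 replicates 1 or 2 or Stage2 replicates 1, 2 or 4 (0.05 to 0.0609). limma-voom called neither (0.146 and 0.157) nor BC1T_13094 (0.0536). BC1T_09180 was not called without the filter (0.0954), after thinning (0.0507) or with the pool number as a replicate block (0.106). The 395 calls became 164, 170, 674 and 258 without Stage1 replicates 1, 2, 3 and 4, and 224 and 220 without Stage2 replicates 1 and 4. DESeq2 called 1018 genes, limma-voom 214, the fit of 8 libraries 161 and the replicate block 261. The share of calls that were higher was 53.7% with TMM and 64.9% with library totals only.

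More fungal genes were called in Stage3 against Stage1, 363 higher and 461 lower. Stage2 pools varied more than Stage3 pools, with biological coefficients of variation of 0.300 and 0.197, which also bears on the number of calls. The fit of 8 libraries gave 1002 calls here and 161 in Stage2 against Stage1. BC1T_16040 fell 53.3-fold, from 138 ± 63.3 to 2.59 ± 0.358 CPM (log2 fold change -5.74 ± 0.57 SE, adjusted p = 0.000626), and BC1T_01444 fell 43.5-fold, from 224 ± 180 to 5.16 ± 0.984 CPM (log2 fold change -5.41 ± 0.50 SE, adjusted p = 0.000626). Their counts, summed over each stage, fell from 1347 to 127 and from 1626 to 255. Mean grapevine counts also fell, from 13.6 M to 1.94 M. Grapevine reads counted on these genes could give such decreases, which was not tested. BC1T_03157 rose from 2.18 ± 1.38 to 31.4 ± 17.6 CPM (log2 fold change 4.03 ± 0.67 SE, adjusted p = 0.00561) and BC1T_15306 from 0.622 ± 0.480 to 9.08 ± 7.72 CPM (log2 fold change 4.02 ± 1.10 SE, adjusted p = 0.0457). The last call was lost without any Stage1 library or without Stage3 replicates 1 or 4 (adjusted p = 0.0760 to 0.134). It was also lost with limma-voom (0.171), without the filter (0.0812) and with the pool number as a replicate block (0.0691). The 824 calls became 457 and 512 without Stage1 replicates 1 and 2, and 331, 496 and 492 without Stage3 replicates 1, 3 and 4, and the 363 higher genes became 238 without Stage1 replicate 4 and 233 with limma-voom. DESeq2 called 1310 genes, and thinning to the smallest fungal total gave 541 of 7665 genes tested. Of the calls, 44.1% were higher with TMM and 68.2% with library totals only, which raised the median by 0.13.

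Between Stage2 and Stage3, edgeR called 0 fungal genes, with a smallest adjusted p of 0.358, while 690 genes had an unadjusted p under 0.05. DESeq2 called 32 genes and limma-voom 0. Without Stage2 replicate 2, edgeR called 3 genes. The 2 stages were not shown to be alike, since a difference below the spread between pools would not be called.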

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

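The splits that part pairs, the comparison of Control profiles by replicate and at matched depth, the direct test of genes with opposite calls and the tests of fungal reads on grapevine genes and of an even background were chosen after the values were seen. The other tests in this part were written down before their results.

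In 5 of 114 groups of 4 libraries tested, 1 library lay far from the others, where chance gives about 1 in 20. VIT_07s0005g03420.t01 had 114 CPM in 1 Stage2 library against 0.753 to 14.3 in the others, and 5.91 CPM in 1 Stage3 library against 0.470 to 0.826. VIT_04s0008g03930.t01 had 183 CPM in 1 Stage2 library against 26.9 to 48.2. BC1T_09180 had 45.6 CPM in 1 Stage1 library against 6.47 to 10.0, and BC1T_16040 had 56.0 CPM in 1 Stage2 library against 14.3 to 20.2.

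A small set of grapevine genes was called in opposite directions at the first and the last stage. There were 23 genes higher at Stage1 and lower at Stage3 than Control (median log2 fold changes 1.08 and -1.44), and 20 genes lower at Stage1 and higher at Stage3 (medians -0.43 and 0.49). A direct edgeR test of Stage3 against Stage1 called 23 and 20 of them, an outcome that choosing genes by opposite calls from the same libraries largely fixes. Independent lists would share 518.5 and 145 genes. So few genes out of the 1790 higher and 538 lower at Stage1 could be false calls at an adjusted p under 0.05.

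The many grapevine genes higher at Stage2 and Stage3 were set against 2 technical explanations. Genes counted from fungal reads alone would follow the ratio of fungal to grapevine counts, which rose by 4.09 on the log2 scale from Stage1 to Stage2. The 4594 genes higher at Stage2 changed by a median of 0.71 (SD 0.90), and 53 of them by 4.09 or more. This argues against fungal reads as the only source of counts for the set. Fungal reads that make up part of a gene's counts would give a smaller change and stay open. Counts that followed the fungal total alone would vary little per fungal count over the 12 infected libraries. Of the 4594 genes, the 53 included, 0 varied by an SD under 0.5 on the log2 scale. Among genes higher at Stage2 or Stage3 the lowest SD was 0.80 and the median 2.35. These values also argue against fungal reads alone for the set. What low counts add to the SDs was not tested, and the 53 genes had no test of their own. The scaling does bear on the number of genes higher: with library totals only, it fell to as few as 2650, from 4278, at Stage3. RLE scaling gave a split near that of TMM, with 47.4% of calls higher at Stage2 and 47.3% at Stage3. How many genes rose may therefore depend on whether scaling such as TMM or RLE is used.

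The small number of grapevine genes between Stage2 and Stage3 was set against depth and spread. With all libraries thinned to 1 grapevine total, Stage2 against Stage1 still gave 5061 genes and Stage3 against Stage2 gave 513, so low counts at the later stages do not account for the gap. The SD of log2 fold changes net of their standard errors was 0.90 between Stage1 and Stage2 and 0.38 between Stage2 and Stage3, a ratio of 0.42, so changes as large were not hidden by the spread between pools. A smaller change of the berry transcriptome late in noble rot is a possible explanation, found and tested on the same data, and the counts of calls themselves varied widely with single libraries.

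Fungal counts in symptomless berries could be early infection or reads carried over from infected libraries. An even background as the only source in all 4 Control libraries is argued against by shares that differed 16.7-fold between them. Replicates 2 and 3 had close shares, 0.0874% and 0.129%, so such a background stays open for those libraries. Over 824 fungal genes that differ between Stage3 and Stage1, the Control profiles lay at a mean of 0.34 (SD 0.35) between Stage1 (0) and Stage3 (1), and the sum of infected libraries at the same depths at 0.67, within the spread set for this test, so carry-over cannot be told apart for the 4 libraries as a set. Replicates 1 and 4, at 0.08 and 0, lay below Stage1 thinned to their depths (0.16 and 0.10), which argues against carry-over from all infected libraries in proportion to their fungal counts, but early infection and carry-over from Stage1 libraries would both give such a position and stay open. Replicates 2 and 3, at 0.68 and 0.61, lay nearer to the summed infected libraries (0.65 each) than to Stage1 at their depths (0.41 and 0.38), and carry-over stays open there.

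Regroupings of the 8 libraries of each comparison were refitted, 35 splits each, to ask how many calls other groupings give. In grapevine genes, only the real split, 1 of 35, gave as many calls in each of the 5 comparisons. Stage1 against Control gave 2328 calls and at most 22 in another split, Stage2 against Control 9294 and 0, Stage3 against Control 8877 and 1, Stage2 against Stage1 8099 and 17, and Stage3 against Stage2 713 and 1. In fungal genes the real split was again 1 of 35 for Stage2 against Stage1 (395 calls, at most 3 in another) and Stage3 against Stage1 (824 calls, at most 0). Each of these comparisons reached the smallest share that 35 splits allow, with no adjustment over comparisons. Mixed splits carry the stage difference as spread within their groups, which holds down their calls. The gap in calls therefore does not exclude chance. In Stage1 against Control, equal pool numbers also met the limit set for pairing. The 22 calls there came from the split of odd against even numbers, which parts no pair. The 8 splits that part all 4 pairs are too few for a share under 5%; the real one gave 2328 calls and the others at most 0. For fungal genes in Stage3 against Stage2, all 35 splits gave 0 calls, as the real one did.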

How the results depend on the processing

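The numbers of calls of the 3 stages against Control and of Stage2 against Stage1 in grapevine genes stayed, as totals, within 1.5 times under RLE scaling, library totals, DESeq2, limma-voom, either filter, the fit of 8 libraries and each left-out library. The lower genes of Stage1 alone went from 538 to 271 without Control replicate 3 and to 1074 with limma-voom. Thinning to the smallest grapevine total removed counts and left 11129 of the 15876 genes to test. It lowered the totals to 1245, 5882, 5889 and 5061. Without Control replicates 1 and 4, chosen after seeing the data, the 3 stages gave 1865, 8176 and 7786 calls against Control. Stage1 against Control gave 1514 calls in odd-numbered and 1231 in even-numbered pools, an alternative also added later, with fewer samples. Stage3 against Stage2 was less stable: DESeq2 called 1192 genes, limma-voom 116 and the fit of 8 libraries 466, and leaving out 1 library gave 177 to 1067. Fungal Stage2 against Stage1 gave 1018 calls with DESeq2, 214 with limma-voom, 161 in 8 libraries and 164 to 674 without 1 library. Fungal Stage3 against Stage1 gave 1310 with DESeq2, 541 of 7665 genes tested after thinning and 331 to 985 without 1 library. Fungal Stage3 against Stage2 gave 32 with DESeq2 and 0 to 3 without 1 library. Where no fewer genes, counts or samples were used, the cause was not tested.

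With the pool number as a replicate block, grapevine calls were 2536, 9302 and 8779 for Stage1, Stage2 and Stage3 against Control, 8060 for Stage2 against Stage1 and 695 for Stage3 against Stage2. Fungal calls were 261 for Stage2 against Stage1, 0 for Stage3 against Stage2 and 683 for Stage3 against Stage1. The block moved no total but 261 by over 1.5 times, with 117 lower genes from 183. In no comparison but Stage1 against Control did the numbers meet the limit set for pairing. In no comparison did every sample correlate best with its own number. In Stage1 against Control the block ended the call of 1 named gene, VIT_06s0004g06830.t01 (adjusted p = 0.0561). Elsewhere VIT_04s0008g03930.t01 (0.0781), BC1T_09180 (0.106) and BC1T_15306 (0.0691) were not called with it, and no other named call was lost. Paired sign-flip tests of the fungal share gave the smallest p possible, 0.125; a block cannot move the ratios of balanced groups. Without 1 library they ranged from 24.2 to 61.9, 131 to 334 and 153 to 392 for Stage1, Stage2 and Stage3 over Control.

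Genes higher at both Stage1 and Stage2 numbered 989 when each had to change at least 2-fold, a stricter call (lower genes 120, from 382), and 1106 to 1325 with Controls split. The grapevine genes with a count in Stage1 minus Control went from 349 at equal depth to -70.5 without thinning, since Control had more counts. The alternatives for gene lists were not run, because no list had members. Depth limits weakly expressed grapevine genes at Stage3, where 1 library held 1.30 M grapevine counts.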

Other observations

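The tests of neighbouring grapevine genes, of identifier blocks and of genes with a count were chosen after the data were seen; the test of neighbouring fungal genes was written down before its result. Identifiers were taken to follow the order along the genome, which the sources used here do not state.

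Increases were enriched in block 16s0100 of the grapevine identifiers at all 3 stages. It held 77 tested genes, and 34 of them, or 44.2%, were higher and 6 lower at Stage1 than in Control, with 11.3% of all tested genes higher (hypergeometric test over 210 blocks, adjusted p = 5.72e-11). At Stage2 45 were higher and 14 lower, and at Stage3 44 were higher and 15 lower (adjusted p for higher genes 1.29e-05 and 4.57e-06). The summed level of the block was 2109 ± 21.4 CPM in Control, 2918 ± 249 in Stage1, 4850 ± 576 in Stage2 and 4232 ± 377 in Stage3 (mean ± SD, n = 4). The median log2 fold change of its genes was 0.33, 1.03 and 0.94 at the 3 stages. Decreases were enriched in block 15s0024, with 26 of 44 genes lower at Stage2 and 25 at Stage3 (adjusted p = 0.00939 and 0.0216, medians -0.60 and -0.75), and in block 12s0057, with 46 of 96 lower at Stage2 (adjusted p = 0.0120, median -0.49). At Stage3 increases were also enriched in block 00s0187, with 14 of 21 genes (adjusted p = 0.0114, median 0.52), and weakly in block 08s0007, with 195 of 568 genes or 34.3% against 26.9% of all genes (adjusted p = 0.00499), where the median of 0.03 shows almost no net shift. Genes of a block are not independent, so these p-values are too small where copies share reads. They were adjusted over blocks within each comparison and direction, with no adjustment over comparisons or directions.

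Neighbouring genes may respond together. In Stage2 against Control, 3249 adjacent pairs of grapevine identifiers were called in the same direction, and 1000 shuffles of the calls gave at most 2731. In fungal genes, Stage3 against Stage1 gave 94 such pairs, and the shuffles at most 48, with a mean of 31.1. Shared reads between similar neighbours and gene models that split 1 gene were not tested and could give the same excess. In grapevine genes of Stage3 against Stage2, 24 pairs lay within the shuffles, which reached 30.

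At equal depth, grapevine genes with a count numbered 16960 on average in Control, 17310 in Stage1, 16238 in Stage2 and 16166 in Stage3. Stage1 was above Control, and Stage2 and Stage3 below it, in all 4 libraries, each with an exact permutation p of 0.0286, the smallest possible. Over the 32 tests of this family the adjusted p was 0.0914, so these differences fail the correction. The 10 most abundant genes held 11.1% of grapevine counts in Control, 10.1% in Stage1, 10.9% in Stage2 and 9.95% in Stage3. The order depended on the number of genes: for the 10 most abundant, Stage2 and Stage3 minus Control were -0.175 and -1.15 percentage points, and for the 100 most abundant 2.30 and 0.885. No unpaired difference of either share passed. Stage1 was below Control in all 4 same-numbered pairs for both shares, and above it in all 4 for the genes with a count at equal depth, each with an exact sign-flip p of 0.125, the smallest that 4 pairs allow, so this test cannot pass.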
